A study of Arabidopsis thaliana with 25 samples.

How the data were processed

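The series compares Arabidopsis thaliana plants that lack histone H1 and carry wild-type MET1, all segregated from a line heterozygous for met1. Per the labels, plants grew for 4 to 5 weeks at 20 to 25 °C with 16 hours of light, 500 ng of leaf DNA was sheared to 100 to 1000 bp, and ligated libraries went through repeated bisulfite conversion. Of 25 samples, the 6 bisulfite libraries, 1 for each of 6 plants, are analysed here. The 19 RNA libraries, among them that of the heterozygous plant, are not analysed here.

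Each library had files for CG, CHG and CHH sites. Each line covered a 50-bp window with a methylation fraction and, in its attributes, the methylated and unmethylated calls and the number of cytosines with calls. The authors deposited the fraction without correction for non-conversion: in every window it equalled methylated calls over all calls within 5e-05. The deposited call counts were raw counts per window. The submitters' processing notes name the build TAIR10 and the tools Bowtie, HISAT2, Cufflinks and deepTools, with no roles. Versions, mapping filters and the handling of duplicate and multiply mapped reads are not given in the sources used here. If duplicates were kept, calls are fewer independent molecules than they appear. The reference used for annotation was checked against the files: of the windows with CG calls on the 5 nuclear chromosomes and the chloroplast, 0 lacked a CG in the reference. Mitochondrial windows are used only as totals, in the closing section, since the mitochondrial sequence of that reference has another length.

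Levels were pooled methylated calls over all calls, per plant and feature. Genes were classed by their mean levels over the 6 plants and their span in the annotation: gbM with CG of at least 5% and CHG and CHH under 5%, TE-like with CHG of at least 10%, low-CG, or other. Windows were summed to 200-bp bins. A bin needed at least 10 calls in every plant, and a gene at least 4 such bins. For each gene a quasi-binomial logistic model with terms for bin and plant was fitted to the call counts, and the plant term was tested with an F test whose dispersion came from the bin-by-plant residuals and was not below 1. P-values were adjusted by Benjamini-Hochberg within each class and context. A gene was counted as varying with an adjusted p under 0.05 and a range between plants of at least 20 percentage points, or 10 points for CHH and for CHG in gbM genes. The p-values measure the spread within a gene and counting error, not the spread between plants of like state, because each plant has 1 library. Neighbouring bins can share reads, and 400-bp bins were tried for that reason.

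The test was tried on simulated calls before it was used for the counts reported. A first version of the dispersion gave too many small p-values for unchanged genes, and it was replaced by an information-weighted dispersion with Satterthwaite degrees of freedom. With that version, 4.54% of unchanged genes had an unadjusted p under 0.05 for CG in gbM genes, 5.68% for CG in TE-like genes, 5.09% for CHG in TE-like genes, 4.45% for CHH in TE-like genes and 3.55% for CHG in gbM genes. In each of these, 0 unchanged genes were counted as varying, a count that also rests on the minimum range. Simulated calls were drawn independently between bins with the median dispersion of each class, so reads shared between bins were not covered. These shares therefore do not give the error rate in the real calls. Losses in 1 plant were simulated only in genes whose level exceeded the minimum range, since a gene below it cannot lose that many points. The shares found below do not hold for genes with lower levels, and gbM genes had a CG level of 11.9% on average. A level reduced by a factor of 10 in 1 plant was found in 98.8%, 100.0%, 98.0% and 100.0% of the changed genes for CG in gbM and for CG, CHG and CHH in TE-like genes. A level cut by 50% was found in 15.0%, 70.0%, 60.0% and 18.8%, and its adjusted p alone passed in 93.8%, 96.0%, 75.0% and 93.8%. For CHG in gbM genes, gains of 15 points were found in 99.0%.

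Features were compared within plants by an exact sign-flip permutation test (2-sided, smallest p 0.031). Profiles of neighbouring genes were compared with 1000 shuffles of gene positions, or 200 for distances over 1 Mb, and the MET1 interval with circular shifts in steps of 10 kb. Overlaps and gene lists were tested with Fisher's exact test, lists only with at least 5 tested members. Fisher's test takes genes as independent, so overlaps were also compared with every rotation of one list along the genome order, a test added after seeing the data. The genes named were set by a rule fixed before the data were examined: MET1, H1.1 and H1.2; the 8 varying gbM genes with the widest CG range; the 4 varying TE-like genes with the widest range in each context; and from each list up to 3 varying members with the widest range and 1 tested member that did not pass with the smallest range. The lists, fixed at the same time, were DNA methylation maintenance and demethylation, RNA-directed DNA methylation, histone H1 and H2A variants, silenced or imprinted loci, flowering time, housekeeping, DNA repair and replication, photosynthesis and NLR immune receptors. A gene that met the rule is not reported here. Levels of named genes come from the tested bins, and those of MET1, H1.1 and H1.2 from the whole gene span. Binomial intervals are 95% Wilson intervals and cover counting error only. For each named gene, 50-base stretches with C read as T were counted on both strands of the nuclear reference, and 27 of 34 genes had under 5% repeated stretches.

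Alternatives covered the coverage minimum, bin size, dispersion, test, minimum range, exons, class limits, background subtraction and leaving out each plant. Thinning every library to the shallowest and leaving out overlapping genes were added after seeing the data. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.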

Results

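Genomic DNA from rosette leaves of 6 Arabidopsis thaliana plants was profiled by whole-genome bisulfite sequencing, which reads an unmethylated cytosine as thymine and leaves a methylated cytosine as cytosine. The plants lacked histone H1, the linker histone that binds between nucleosomes, and carried 2 wild-type copies of MET1, the methyltransferase that copies CG methylation onto new DNA strands. They had segregated from an h1 line heterozygous for a met1 mutation. Each plant gave 1 library, and the plants are numbered 1 to 6 as in the labels. The files held between 51785831 calls (plant 3) and 88635497 calls (plant 5) at nuclear CG sites. This was 9.38 to 16.0 calls per covered CG site. CHG and CHH sites, where H is any base except G, had 8.6 to 14.4 and 7.79 to 12.6 calls per covered site.

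The labels give the 6 bisulfite libraries as a single group, so the comparison made was between plants, gene by gene. It asks which genes carried different methylation in plants of the same genotype and common descent. With 1 library per plant, the error of a gene's difference between plants is the spread between 200-bp bins of that gene and the counting error of its calls. All coordinates are TAIR10.

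The targeted genes were examined first. MET1 (AT5G49160, chromosome 5, 19932114 to 19938470) had a CG level of 11.2% ± 0.836 (SD, n = 6) over its gene span. Its CHG level was 21.0% in plant 1, 7.56% in plant 2, 0.239% in plant 3, 3.47% in plant 4, 0.167% in plant 5 and 7.21% in plant 6, from at least 4037 calls each. H1.1 (AT1G06760, chromosome 1, 2076504 to 2077767) and H1.2 (AT2G30620, chromosome 2, 13044931 to 13046682) had mean CG levels of 0.157% ± 0.0826 and 0.291% ± 0.281 (SD, n = 6). These methylation levels do not test the genotype in the labels.

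Across the nuclear genome, the 6 plants had similar methylation levels. The CG level was 14.7% ± 0.58, the CHG level 7.12% ± 0.599 and the CHH level 1.63% ± 0.109 (SD, n = 6). Chloroplast DNA, taken as unmethylated, read 0.12% in CG, 0.0937% in CHG and 0.0815% in CHH. Of 27444 nuclear protein-coding genes, 4964 had gene-body methylation (gbM), which means CG methylation of at least 5% with CHG and CHH each under 5%. Another 1744 genes carried CHG methylation of at least 10% and are called TE-like, since transposable elements carry CHG methylation too. The name marks this CHG limit only. No CG or CHH limit was set, so the class can hold genes methylated unlike transposable elements. The low-CG class held 19117 genes, and 1619 fitted no class. The CG level was 11.9% ± 1.89 in gbM genes, 41.1% ± 1.22 in TE-like genes and 50.5% ± 1.71 in 4843 annotated pseudogenes (SD, n = 6). The gbM and TE-like classes were set from the levels of these plants, so differences between them follow partly from their definition and are not read as results. Annotated pseudogenes, many of them transposon genes, were not chosen by level, unlike TE-like genes. They exceeded TE-like genes in 6 of 6 plants in CG, CHG and CHH, by 9.41, 17.2 and 3.05 percentage points. The exact sign-flip permutation test gave p = 0.031 (2-sided; adjusted p = 0.031 over 9 comparisons), the smallest value that 6 plants allow. The excess holds for pooled calls, which weight genes with more calls. As a mean over genes, TE-like genes were at 52.7% in CG and 27.7% in CHG, and pseudogenes were not computed that way.

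Plants differed more within gbM genes than over the genome. The CG level of this class was 14.4% in plant 1, 13.3% in plant 2, 11.8% in plant 3, 12.3% in plant 4, 10.0% in plant 5 and 9.44% in plant 6. Its highest plant was 1.53 times its lowest, against 1.1 times for the nuclear genome. The CG ratio was 1.58 in low-CG genes, 1.09 in TE-like genes and 1.1 in pseudogenes, so a high ratio is not particular to gbM genes. In points the spread of pseudogenes was similar, from 48.4% to 53.3%. Within TE-like genes the CG level spanned 39.7% to 43.2% and the CHG level 14.1% to 23.5%. With 1 library per plant these class averages have no test between plants.

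Among gbM genes, 1083 of the 4849 genes tested (22.3%) varied between plants in CG methylation. A gene was counted where the quasi-binomial F test of the plant term gave a Benjamini-Hochberg adjusted p under 0.05 and the highest and lowest plants differed by at least 20 percentage points. The adjusted p alone passed in 3358 genes. The share depends on the class limit: with a mean CG level of at least 10%, 1038 of 2679 genes varied (38.7%). The median range of the 1083 varying genes was 27.0 points, and the median gene had 1400 CG calls per plant. DCL3 (AT3G43920, chromosome 3, 15753387 to 15760859), the Dicer-like enzyme that makes the small RNAs of RNA-directed DNA methylation, read 59.7% in plant 1 (95% Wilson interval 57.7 to 61.7) and 59.3% in plant 3. It read 26.1% in plant 2 and 29.0% in plant 4 (interval 27.4 to 30.6), and 0.258% in plant 5 and 0.149% in plant 6 (interval 0.0638 to 0.349). The adjusted p of DCL3 was 1.6e-69. CCT (AT4G00450, chromosome 4, 200874 to 211309), a subunit of the Mediator complex, was at 60.1%, 59.7% and 61.0% in plants 1, 2 and 4. It was at 27.2% and 30.9% in plants 3 and 5 and at 0.197% in plant 6. The adjusted p of CCT was 5.4e-103. Intervals cover counting error only.

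The other 6 of the 8 genes with the widest CG ranges showed levels of the same kind. AT4G33585 (chromosome 4, 16141535 to 16142345) spanned 78.1 points, from 2.2% in plant 6 to 80.2% in plant 1. The adjusted p of AT4G33585, from 4 bins, was 0.00053. AT3G48475 (chromosome 3, 17954727 to 17956096) spanned 69.4 points, with 0.114% in plant 5 and 69.5% in plant 4. AT3G28630 and AT3G28635 (chromosome 3, 10728951 to 10730898 and 10729313 to 10731391) overlap on opposite strands and so share windows. They had no methylated call in plant 5, 0 of 1190 and 0 of 1215 calls with upper Wilson bounds of 0.322% and 0.315%, against 67.5% and 65.1% in plant 1. The neighbouring AT3G24870 and AT3G24880 (chromosome 3, 9074665 to 9085419 and 9085720 to 9096689) reached 62.7% and 67.3% in plant 3 and fell to 0.885% and 0.988% in their lowest plants. Their values are uncertain one against the other, because 78.0% of the 50-base stretches of each occur more than once in the converted reference.

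Levels in the 1083 varying gbM genes gathered near 0 and near 50% of the gene's highest plant, with a smaller share near its top. Each plant's level was expressed as a percentage of the gene's highest plant, which is at 100% by construction and was left out of these shares. Of the other 5415 gene and plant values, 23.7% lay under 25%, 60.2% lay from 25 to 75%, and 16.0% lay at 75% or above. The intermediate values had a median of 47.9% and an SD of 7.05 points. In 649 genes, at least 1 plant had under 5% of the highest level. Over the genes in which it was not itself the highest, plant 1 had 40.3% of its values at 75% or above and 15.8% under 25%. Plant 6 had 4.17% at 75% or above and 39.5% under 25%, and plant 5 had 4.91% and 39.9%.

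**Figure D1:**
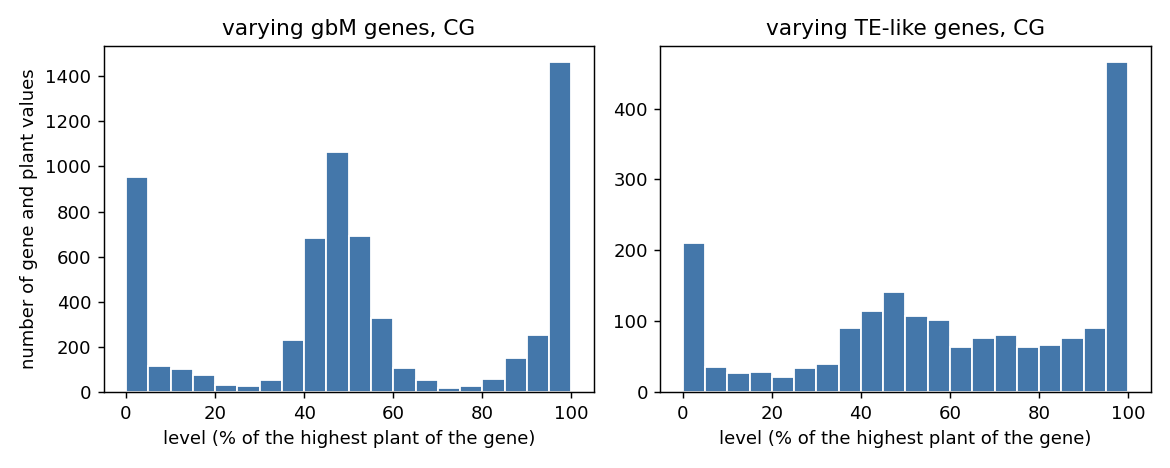
Number of gene and plant values (vertical axis) by CG level as a percentage of the gene's highest plant (horizontal axis), for the 1083 varying gbM genes (left) and the 323 varying TE-like genes (right) over 6 plants. The last bar includes each gene's highest plant, 1083 and 323 values at 100% by construction. The other gbM values form peaks near 0 and around 47.9% with a smaller one near the top, and the TE-like values fill the range above the middle more evenly.

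**Figure D2:**
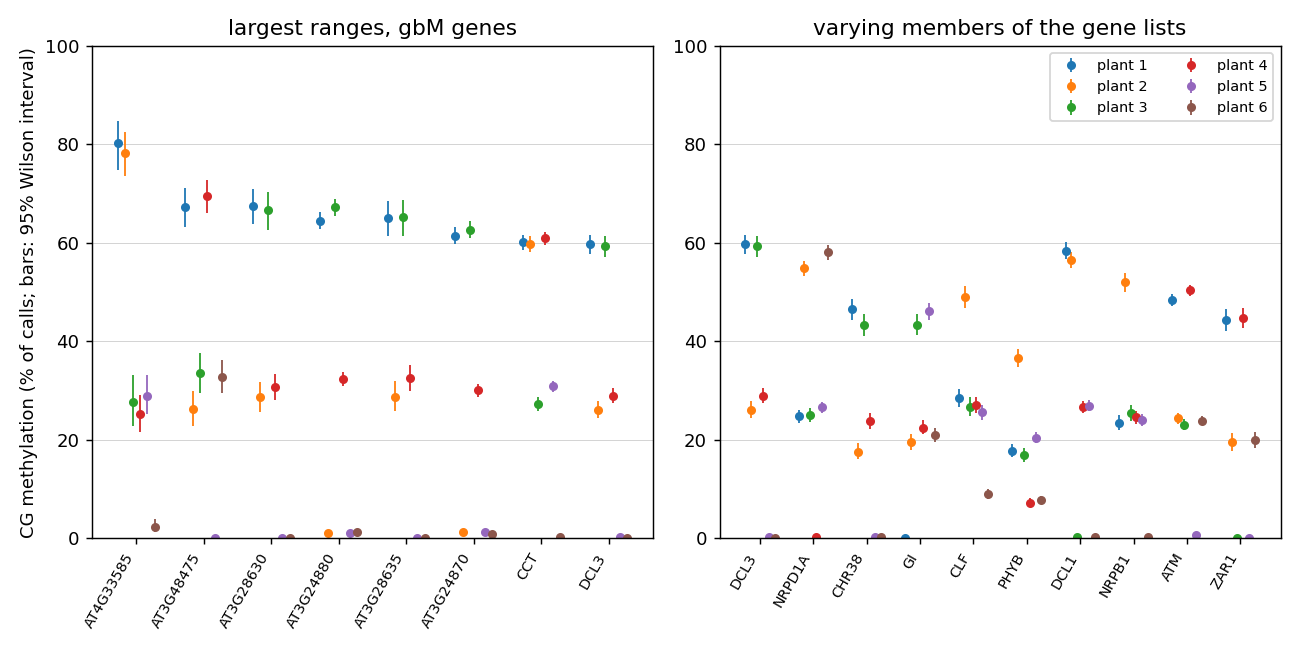
CG methylation of each of the 6 plants (points, % of calls) with 95% Wilson intervals for the 8 gbM genes with the widest ranges (left) and for the varying members of the gene lists (right). DCL3 sits at 59.7% and 59.3% in plants 1 and 3, at 26.1% and 29.0% in plants 2 and 4, and under 1% in plants 5 and 6.

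Neighbouring varying genes had similar patterns over the plants. Between varying gbM genes less than 50 kb apart, the mean Pearson correlation of the 6-plant profiles was 0.98 over 1708 pairs. Shuffled gene positions gave 0.162 (permutation p = 0.000999, the smallest that 1000 shuffles can give). Over all tested gbM genes, varying or not, it was 0.722 over 17966 pairs, against 0.0433 in shuffled positions, and with Spearman correlation in varying genes it was 0.834. The mean Pearson correlation of varying genes was 0.972 at 50 to 200 kb, 0.935 at 200 to 1000 kb, 0.853 at 1000 to 2000 kb, 0.669 at 2000 to 5000 kb and 0.344 beyond 5000 kb, each above its shuffled mean of 0.162 (permutation p = 0.00498 for the 3 longest classes, the smallest that 200 shuffles can give). Genes are not independent replicates, so the correlations describe these 6 plants. On chromosome 3, for example, plant 5 had a low level in most 500-kb blocks from 9 Mb to the end of the chromosome, and plant 6 had a low level from 9 to 16.5 Mb. On chromosome 1, plant 1 was at 1.88%, 1.86%, 5.39%, 3.11% and 0.874% of the highest plant in the 5 blocks from 7000001 to 9500000. In these blocks plants 3 and 5 were at 92.7% to 97.4%.

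**Figure D3:**
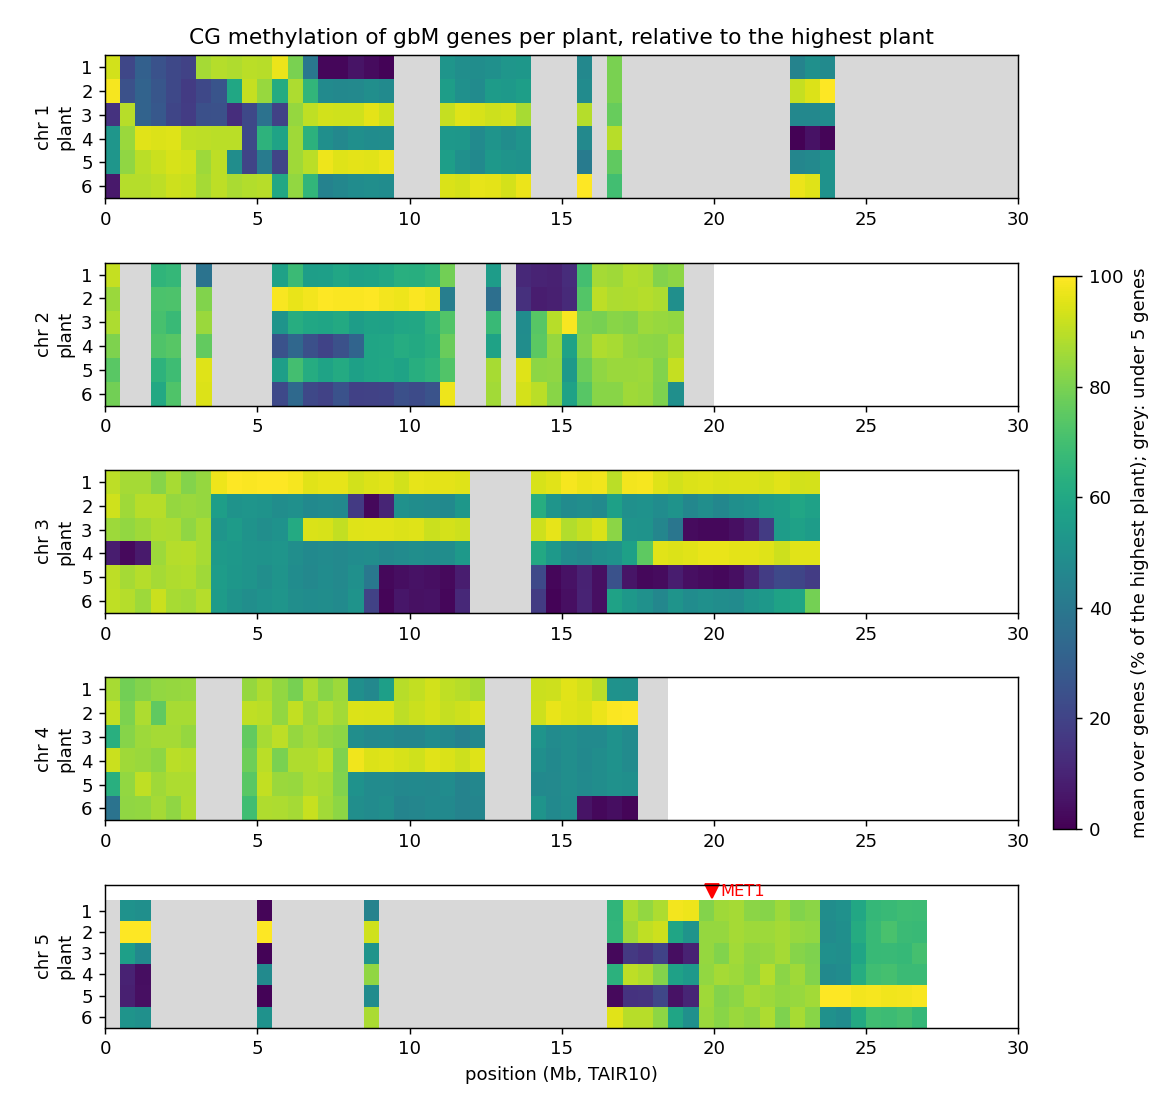
CG level of gbM genes in 500-kb blocks along the 5 chromosomes (horizontal axis, Mb), 1 row per plant, as the mean over genes of the level relative to the gene's highest plant (colour, %); grey blocks hold under 5 genes and MET1 is marked in red. Levels are similar over runs of blocks and change at places that can differ between plants, as on chromosome 3, where plant 3 is at 51.0%, 61.3% and 94.4% in the 3 blocks from 5500001 to 7000000 and plant 2 at 48.9%, 50.2% and 47.3%.

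**Figure D4:**
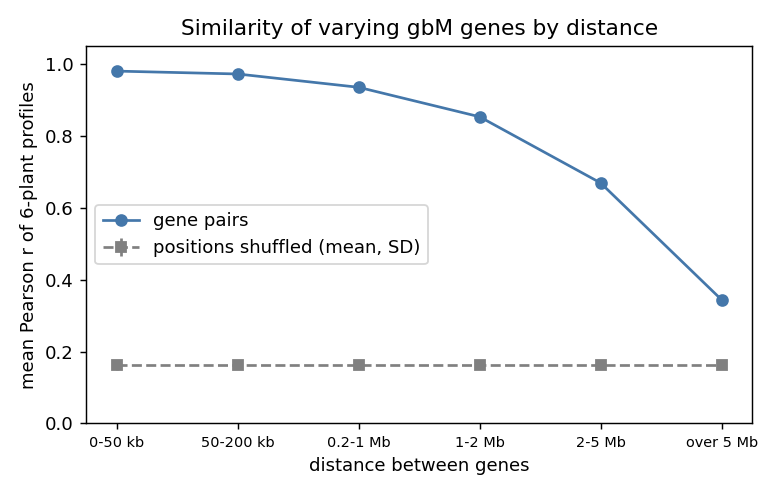
Mean Pearson correlation of 6-plant CG profiles (vertical axis) between varying gbM genes, by distance (horizontal axis), with the mean and SD of shuffled positions in grey. It falls from 0.98 under 50 kb to 0.344 beyond 5000 kb and stays above 0.162, the shuffled mean.

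The varying genes were unevenly spread over the chromosomes. Chromosome 3 had 474 varying genes of 1570 tested (30.2%), chromosome 1 had 205 of 791 (25.9%), chromosome 2 had 171 of 727 (23.5%), chromosome 4 had 192 of 1042 (18.4%) and chromosome 5 had 41 of 719 (5.7%). No test was made between chromosomes, since neighbouring genes are not independent.

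Gene-body methylation itself was unevenly spread. It was found in 29.2% of protein-coding genes on chromosome 3, 25.4% on chromosome 4, 17.7% on chromosome 2, 11.7% on chromosome 5 and 11.2% on chromosome 1. From 24 Mb to the end of chromosome 1, 11 of 1716 genes were in the gbM class (0.641%), a region singled out after its values were seen.

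**Figure D5:**
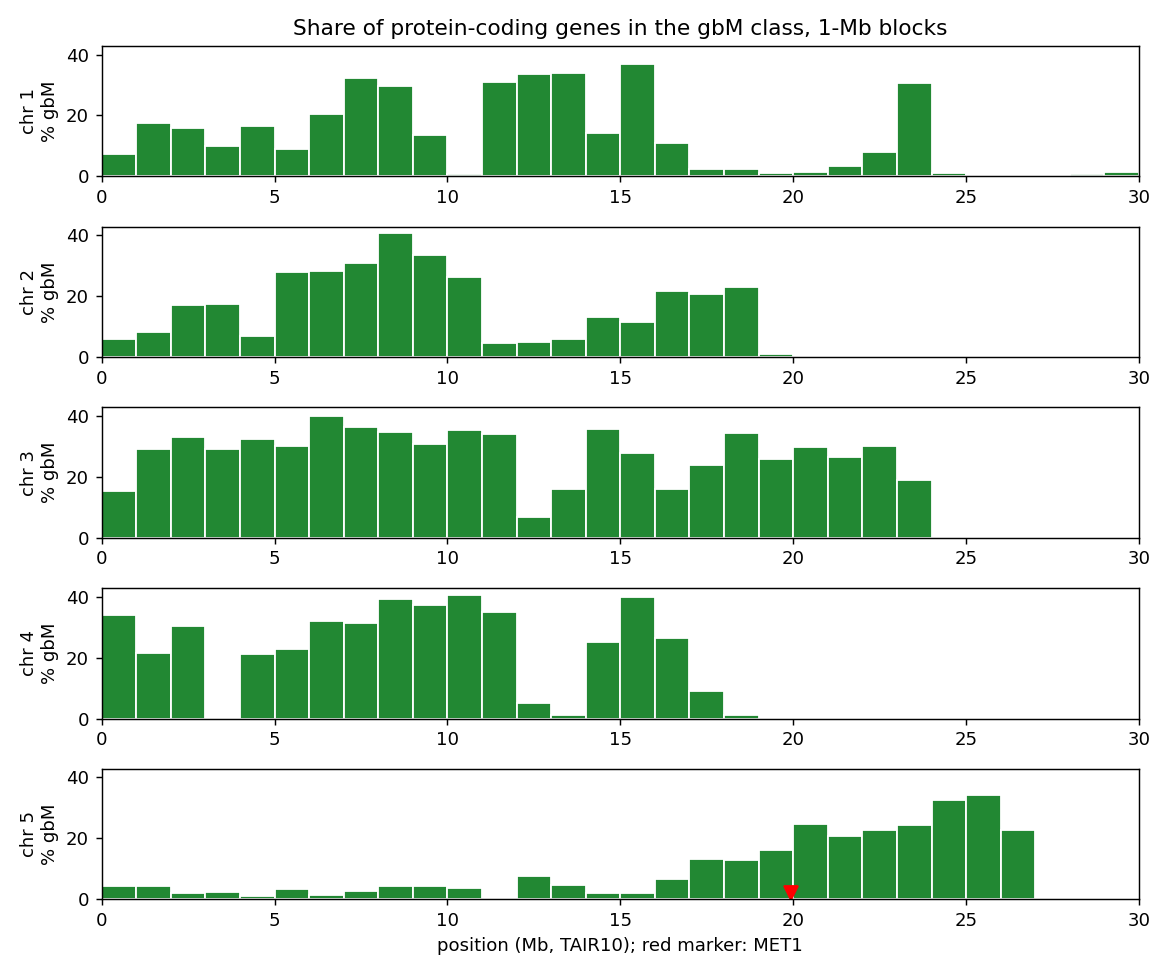
Share of protein-coding genes in the gbM class (vertical axis, %) in 1-Mb blocks along the 5 chromosomes (horizontal axis, Mb), with MET1 marked in red. The share falls to 0.858% between 10000001 and 11000000 on chromosome 1, next to a block at 31.1%.

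The MET1 region was compared with the rest of the genome, because a plant with wild-type MET1 must carry wild-type chromosome at that place. The 106 gbM genes within 1 Mb of MET1 were at 76.9% of their highest plant on average, against 64.9% for the other 4743 genes, a difference of 12 points that was positive in 6 of 6 plants. It lay at percentile 78.7 of 11843 circular shifts of the interval (permutation p = 0.422, 2-sided), so this test did not separate it from other places. The relative level is high where plants are alike, and genes unmethylated in all plants are not in the gbM class. Shifts that held few genes were kept, which widens the comparison. The test therefore cannot show that the region is like the rest of the genome. With absolute levels the sign turned, at -0.502 points.

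TE-like genes varied in both CG and CHG methylation. In CG, 323 of 1291 genes tested varied (25.0%), with a median range of 35.8 points, and in CHG 668 of 1301 varied (51.3%), with a median range of 28.9 points. The TE-like class was set by the mean CHG level of the same plants, so genes high in CHG in only some plants can enter it. The share of 51.3% therefore holds only within this limit and follows partly from it. The CG and CHG sets shared 230 genes of the 1264 tested in both contexts, against 162 for independent lists (Fisher's exact test, 2-sided, odds ratio 3.44, p = 2.71e-19). Fisher's test takes genes as independent, which neighbouring genes are not. Against 1264 rotations of the CHG list along the genome, which keep neighbours together and were chosen after seeing the data, the highest other overlap was 193 (permutation p = 0.000791, the smallest these rotations can give). In the shared genes the CG and CHG profiles over the plants had a median correlation of 0.983, and in 137 of the 230 the same plant was lowest in both contexts. No shuffled value was computed for this correlation. AT3G44006 (chromosome 3, 15796133 to 15796837) had a CG level of 92.0% and 93.3% in plants 1 and 3, 33.0% and 35.4% in plants 2 and 4, and 0.11% and 0.147% in plants 5 and 6. The adjusted p of AT3G44006 in CG was 6.2e-08. AT3G50320 (chromosome 3, 18653731 to 18654717) had a CG level of 93.6% in plant 4 and 0.173% in plant 5. Its CHH level was 18.7% in plant 1, 16.1% in plant 4 and 0.185% in plant 5.

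For CHG, AT4G03165 (chromosome 4, 1399378 to 1400291) was at 67.2% in plant 6 and at 0.191% in plant 4, with 24.8% or less in plants 1 to 5. The adjusted p of AT4G03165 in CHG was 2.7e-08. WAK5 (AT1G21230, chromosome 1, 7429895 to 7432477), a member of the wall-associated kinase family, had a CHG level of 65.8% in plant 5, 49.4% in plant 3 and 0.307% in plant 1, with 16.3% to 26.6% in the other plants. The adjusted p of WAK5 in CHG was 8.6e-31. AT1G25025, AT1G25112, AT1G25141 and AT1G24851 also met the naming rule and lie between 8778280 and 8818395 on chromosome 1. AT1G25025 and AT1G25112 had CG levels of 0.217% and 0.129% in plant 1 and of 94.1% and 94.4% in plant 5. AT1G25141 and AT1G24851 had CHG levels of 8.33% and 0.262% in plant 1 and of 73.0% and 64.4% in plant 5. Their values are uncertain, since 96.9% to 100.0% of their 50-base stretches are repeated in the converted reference.

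CHH methylation varied in 52 of 1357 TE-like genes (3.83%), with a minimum range of 10 points. AT1G48953 (chromosome 1, 18110814 to 18111463) had a CHH level of 30.6% in plant 1 and 3.95% in plant 5, and 30.8% of its 50-base stretches are repeated. AT3G25460 (chromosome 3, 9231581 to 9232666) had a CHH level of 21.5% in plant 3, 18.6% in plant 1 and 2.45% in plant 6. AT1G25141 ranged in CHH from 1.64% in plant 1 to 19.6% in plant 3. Of the varying CHH genes, 26 also varied in CG, against 12.3 for independent lists (Fisher's exact test, 2-sided, p = 2.63e-05; permutation p = 0.00232 from rotations). With 50-bp windows as units, 98 of 1711 genes varied (5.73%), and with 400-bp bins 25 of 995 (2.51%). The count also depends strongly on the minimum range: 245 genes passed with 50% of it and 8 with 1.5 times it.

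CHG methylation of gbM genes varied in 138 of 4848 genes (2.85%), again with a minimum range of 10 points. Of these, 28 also varied in CG, against 30.6 for independent lists (Fisher's exact test, 2-sided, odds ratio 0.889, p = 0.677; permutation p = 0.792 from rotations). The count depends strongly on the minimum range: 6 genes passed with 1.5 times the minimum and 783 with 50% of it. Without genes that overlap another annotated gene, the count was 76 of 3200. The gbM class was set by the mean CHG level of the same plants, so genes above its CHG limit were removed before the test. MET1, with a CHG level of 21.0% in plant 1 and a mean of 6.6%, was left out in this way. The share of 2.85% and the overlap with CG therefore hold only within this limit, and the low share follows partly from it.

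Of the 9 gene lists, RNA-directed DNA methylation had the largest share of varying genes among lists with at least 5 tested members. CG methylation varied in 4 of its 6 tested gbM genes (4 adjusted over the list alone), against 22.3% of all tested gbM genes (Fisher's exact test, 2-sided, p = 0.0251, adjusted p = 0.0753 over 3 lists, so the excess did not pass). Besides DCL3, NRPD1A (AT1G63020, chromosome 1, 23354685 to 23362589), the largest subunit of RNA polymerase IV, had a CG level of 54.8% and 58.1% in plants 2 and 6, 24.8% to 26.6% in plants 1, 3 and 5, and 0.207% in plant 4. CHR38 (AT3G42670, chromosome 3, 14755798 to 14760629), the CLSY1 chromatin remodeller that works with that polymerase, had a CG level of 46.5% in plant 1 and 0.223% in plant 6. AGO6 (AT2G32940, chromosome 2, 13971916 to 13977521), an Argonaute of the same pathway, had a range of 12.2 points and did not reach the minimum. Fisher's test takes genes as independent, which DCL3 and CHR38 may not be. Both lie on chromosome 3, with their highest levels in plants 1 and 3 and their lowest in plants 5 and 6.

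Among flowering time genes, 5 of 13 tested members varied in CG (5 adjusted over the list alone; Fisher's exact test, 2-sided, p = 0.181, adjusted p = 0.271). GI (AT1G22770, chromosome 1, 8061751 to 8067790), a clock and photoperiod regulator, was at 46.1% in plant 5, 43.4% in plant 3 and 0.0766% in plant 1. CLF (AT2G23380, chromosome 2, 9955092 to 9960386), a histone H3 lysine methyltransferase of the Polycomb group, ranged from 8.93% in plant 6 to 49.0% in plant 2. PHYB (AT2G18790, chromosome 2, 8139756 to 8144461), a red-light receptor, ranged from 7.26% in plant 4 to 36.6% in plant 2. FPA (AT2G43410, chromosome 2, 18025247 to 18031255) was at 16.7% ± 1.15 (SD, n = 6 plants) and did not pass.

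Housekeeping genes varied in 2 of 6 tested members (2 adjusted over the list alone; Fisher's exact test, 2-sided, p = 0.621, adjusted p = 0.621). DCL1 (AT1G01040, chromosome 1, 23121 to 31227), the Dicer-like enzyme of microRNA processing, had a CG level of 58.4% and 56.5% in plants 1 and 2, 26.6% and 26.9% in plants 4 and 5, and 0.203% and 0.189% in plants 3 and 6. NRPB1 (AT4G35800, chromosome 4, 16960558 to 16968128), the largest subunit of RNA polymerase II, was at 52.0% in plant 2 and 0.272% in plant 6. The clathrin heavy chain gene AT3G08530 (chromosome 3, 2586804 to 2595654) was at 16.3% ± 0.73 and did not pass.

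Lists with fewer than 5 tested members were counted without a test. DNA repair and replication had 1 varying gene of 4 tested (1 adjusted over the list alone). This was ATM (AT3G48190, chromosome 3, 17801289 to 17828553), a kinase of the DNA damage response, with a CG level of 50.4% in plant 4 and 0.596% in plant 5. BRCA1 (AT4G21070, chromosome 4, 11247991 to 11252757) had a range of 6.36 points. NLR immune receptors had 1 of 2 (1 adjusted over the list alone), ZAR1 (AT3G50950, chromosome 3, 18935674 to 18938799), at 44.8% in plant 4 and 0.0915% in plant 5. Genes of methylation maintenance and demethylation had 0 of 3 (0 adjusted over the list alone). In 2 of them the quasi-binomial test gave an unadjusted and an adjusted p under 0.05, but no range reached 20 points, the widest being 19.5. IBM1 (AT3G07610, chromosome 3, 2425884 to 2433113), a histone demethylase, was at 12.3% ± 0.482 in its tested bins. Silenced or imprinted loci had 0 of 2 (0 adjusted over the list alone). In 1 of them the unadjusted p and the p adjusted over all tested gbM genes were under 0.05, but no range exceeded 4.92 points. FWA (AT4G25530, chromosome 4, 13038360 to 13042464) was at 13.8% ± 1.47 (SD over 6 plants). All 12 photosynthesis genes and 8 of 9 histone H1 and H2A genes were in the low-CG class, and neither list had a tested gbM gene.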

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

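The tests on the COPIA93 elements in this part were chosen after the depth had been seen. Of 81 sets of 6 plant values examined, 6 had a plant far from the others, and chance alone gives about 4.05.

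EVADE (AT5G17125, chromosome 5, 5630538 to 5634764) and the related AT1G34967 (chromosome 1, 12755620 to 12759846), retrotransposons of the COPIA93 family that the annotation lists as pseudogenes, had many more calls than the rest of the genome. Depth at CHH sites relative to the median nuclear window was 14.5 to 19.8 over EVADE in plants 1 to 5 and 5.31 in plant 6, which stood apart. For AT1G34967 it was 9.07 to 12.2 in plants 1 to 5 and 3.59 in plant 6. The CG level of EVADE was 1.77% to 4.29% in plants 1 to 5 and 12.5% in plant 6.

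A lower organelle depth in plant 6 is argued against as the cause, since the lower of its mitochondrial and chloroplast depth ratios to the median of the other plants was 0.858, and the values above are already relative to nuclear depth. More calls from unmethylated DNA are argued against by other pseudogenes with CG under 5%, whose relative depth had a 95th percentile of 1.41. Sharing of reads between the 2 elements, which have 82.4% of their converted 50-base stretches in common, cannot create depth, and their depths summed to at least 8.89 in every plant, against a median of 2.0 copies per stretch in the reference. Additional copies of the element remain a candidate explanation, as a hypothesis: the 10 kb on each side of EVADE had a relative depth no farther from 1 than 1.08. Where such copies lie, and whether they are inserted or outside the chromosomes, was not tested.

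The CHG level of MET1 was 21.0% in plant 1, against 0.167% to 7.56% in the other plants. AT4G03165 had a CHG level of 67.2% in plant 6, against 0.191% to 24.8% in the others. H1.1 had 0 methylated CG calls in plant 3 (a level of 0.0% of 921 calls), against 0.156% to 0.242% in the others, all within a few calls of the chloroplast background of 0.12%. The upper limit in plant 3 was 0.326%, from 3 calls allowed at a count of 0, and is not a Wilson bound. The mitochondrial CG level was 3.32% in plant 1, against 6.32% to 7.88% in the others.

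Mitochondrial windows, used only in this closing section, read a mean of 6.47% in CG, 3.87% in CHG and 0.75% in CHH, above the chloroplast level in each context. Methylated mitochondrial CG calls per site, relative to nuclear depth, were 0.369 ± 0.0251 (SD, n = 6), while total mitochondrial depth relative to nuclear depth was 10.7 in plant 1 and 4.66 to 6.28 in the others. Chromosome 2 holds a region of mitochondrial DNA, and its reads were not separated from the mitochondrial windows. The mitochondrial levels are therefore not read as methylation of the mitochondrial genome, and their source was not tested.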

How the results depend on the processing

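Of 137 values under alternative settings, 116 stayed the same, 20 moved and 1 changed sign. Counts of varying genes are the same within 1.5 times (79, with 13 moved), levels within 1 SD between plants (20, with 7 moved), and tested differences on the same side of 0 and of the threshold (17). The cause of these moves was not tested, except that a wider or narrower minimum range admits fewer or more genes by construction. With 50% of the minimum range, the counts of varying genes were 2625 for CG in gbM genes, 502 for CG, 1009 for CHG and 245 for CHH in TE-like genes, and 783 for CHG in gbM genes. With 1.5 times the minimum they were 415, 203, 288, 8 and 6. For CHH in TE-like genes, 50-bp windows gave 98 of 1711 tested and 400-bp bins 25 of 995. For CHG in gbM genes, leaving out overlapping genes, an alternative chosen after seeing the data, gave 76, with fewer genes tested.

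A mean of window or gene fractions in place of pooled calls gave nuclear levels of 19.0% in CG and 9.01% in CHG, gbM levels of 1.22% in CHG and 0.167% in CHH, and TE-like levels of 52.7% in CG and 27.7% in CHG. Subtracting the chloroplast background gave 0.127% for CHH in gbM genes. Around MET1, absolute levels reversed the difference to -0.502 points, and neither value passed its test. Without each plant in turn, the counts ranged from 855 to 1040 for CG in gbM genes, from 276 to 307 for CG, 508 to 641 for CHG and 39 to 51 for CHH in TE-like genes, and from 96 to 130 for CHG in gbM genes. The correlation of neighbouring genes ranged from 0.974 to 0.983, and was 0.722 over all tested gbM genes and 0.834 with Spearman correlation. The MET1 difference ranged from 10.3 to 13.9 points. Libraries thinned to the shallowest, also chosen after seeing the data, gave 1098 for CG in gbM genes, 324 for CG, 675 for CHG and 54 for CHH in TE-like genes, and 139 for CHG in gbM genes, so unequal depth moved none of these 5 counts by over 1.5 times. No paired analysis was possible because the bisulfite libraries form 1 group, and there is no other group to pair them with; the comparison of features within plants is not one between groups.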

Other observations

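The tests on mixtures, on the position of MET1 by chance and the tally by 1-Mb blocks were chosen after the results had been seen. Those on depth around MET1 and on chromosome segments were fixed before their values were computed.

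Gene-body methylation was nearly absent from long stretches of the genome, with genes classed by the mean of the 6 plants. In 30 of the 106 1-Mb blocks with at least 100 protein-coding genes, under 5% of genes were in the gbM class, 160 of 7455 genes (2.15%). In 52 blocks the share was 20% or more, 3983 of 13236 genes (30.1%). From 24 Mb to the end of chromosome 1, 11 of 1716 genes (0.641%) were gbM, and on chromosome 5 the share was 11.7%, against 29.2% on chromosome 3. On chromosome 1 the block from 10000001 to 11000000 had 0.858%, between 13.5% and 31.1% on its sides. On chromosome 5 the share was 2.1%, 6.57%, 13.3%, 12.8%, 16.2% and 24.7% in the blocks from 15000001 to 21000000. No explanation was tested.

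CHH methylation was higher in plants 5 and 6 than in the others in CHG-rich blocks and lower in the remaining blocks, and CHG methylation did not show this contrast. In 183 blocks of 100 kb with a mean CHG level of 20% or more, the CHG level was 39.4% in plants 5 and 6 and 28.3% to 33.0% in plants 1 to 4, and the CHH level was 7.93% and 7.95% against 5.34% to 6.51%. In the other 1010 blocks the CHH level was 0.533% and 0.547% in plants 5 and 6 and 0.715% to 0.866% in the others, while the CHG level was 3.38% in plant 5, 4.02% in plant 6 and 3.25% to 3.97% in the others. These block levels have 1 library per plant and no test between plants. Annotated pseudogenes, many of them transposon genes, varied in CG in 768 of 3768 tested (20.4%), with ranges up to 94.0 points.

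The intermediate CG levels of varying gbM genes may come from an equal mixture of methylated and unmethylated copies, as in a plant heterozygous for the methylation state. Calls fell where methylation was higher. Across the 6 plants, the median slope of unmethylated on methylated depth was -1.27 in varying gbM genes (bootstrap interval over genes -1.28 to -1.25). That interval takes genes as independent, which neighbouring genes are not, so it is too narrow. The median slope was -1.5 in varying TE-like genes and -1.46 in varying pseudogenes, where equal yield gives -1. An equal mixture then predicts 47.8% of the highest plant for gbM genes, and 85.8% of their intermediate values lay within 10 points of it (bootstrap interval over 24 blocks of 5 Mb, 79.4 to 90.5), where an even spread gives 40%. In TE-like genes 53.3% lay within 10 points of the predicted 45% (interval 41.8 to 63.1), which leaves the hypothesis open there. In pseudogenes 30.3% lay within 10 points of the predicted 42.6% (interval 25.3 to 34.8). Their intermediate values had a median of 58.7% and an SD of 13.8 points. These values argue against an equal mixture with an unmethylated copy, which the prediction assumes. Only 66 of 768 varying pseudogenes had a plant under 5% of the highest level, against 649 of 1083 varying gbM genes. An equal mixture with a partly methylated copy was not tested. A mixture of copies within cells and a mixture between cells were not distinguished.

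Few gbM genes varied around MET1: 5 of 106 within 1 Mb (4.72%), against 22.7% elsewhere, with median ranges of 4.68 and 11.7 points. The whole of chromosome 5, which holds MET1, had 41 of 719 (5.7%), so a low share is not particular to the interval. Plants can differ where the share is low. From 25000001 to 26000000, 0 of 103 tested genes varied. There plant 5 was at 97.7% to 98.8% of the highest plant, and the others at 66.5% to 71.1%. From 20000001 to 21000000, mostly inside the interval, 0 of 61 varied and all plants were at 81.1% to 86.6%. From 19000001 to 19500000, also inside, plant 1 was at 97.5% and plants 3 and 5 at 9.65% and 10.3%. These shares therefore do not show that the interval is like its chromosome. Fewer calls per gene are argued against as the whole cause, since the median calls per gene inside were 0.871 of those outside, above the bound of 0.8 set beforehand. A chance position remains a possible explanation, because 25.5% of 8575 circular shifts had a share as low. A hypothesis of common descent of this segment in all 6 plants was not tested.

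The hypothesis that methylation states travel with chromosome segments was tested outside CG in gbM genes. For the 138 gbM genes varying in CHG, the mean profile correlation under 50 kb was 0.931 over 42 pairs, against a highest shuffled value of 0.376. For TE-like genes it was 0.925 in CG over 176 pairs (highest shuffled value 0.188) and 0.854 in CHG over 569 pairs (highest shuffled value 0.241). Permutation p was 0.000999 in each, the smallest that 1000 shuffles can give. Leaving out pairs closer than 5 kb gave 0.93, 0.922 and 0.851, so the similarity did not rest on those pairs alone. Repeated TE-like genes farther apart, such as AT1G25025 and AT1G25112, may share reads. They were kept, and no test without them was made. The 6 plants carry no genotype markers in these data, so segments themselves were not observed.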
